A study of Homo sapiens with 14 samples.

How the data were processed

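Directional RNA sequencing had been run on total RNA of 4 human prostate cancer cell lines, with 1 library for each line and treatment and 14 libraries in all. LNCaP and VCaP are established androgen receptor positive lines, and each gave 5 libraries. LTAD and VCaP-LTAD are names for cells kept in medium with 10% charcoal-stripped serum, which is poor in steroids, and each gave 2 libraries. Per the labels, LNCaP and VCaP cells spent 3 days in 2.5% stripped serum before treatment. Cells with siAR, a small interfering RNA against the androgen receptor gene AR, received 10 nM of it for 48 h before the hormone. The labels name no library with a control siRNA, so effects of siRNA treatment itself cannot be told apart from those of AR loss. Hormone treatment was ethanol vehicle or 10 nM dihydrotestosterone (DHT), the potent natural androgen, for 24 h. The antiandrogen bicalutamide was added to DHT in 1 library of LNCaP and 1 of VCaP, and the labels give no dose for it. The labels do not state from which cells the LTAD and VCaP-LTAD lines were raised, and LTAD was taken to stem from LNCaP and VCaP-LTAD from VCaP.

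The deposited tables hold raw read counts per transcript of uniquely mapped reads on hg19, 1 table per library for GENCODE non-coding transcripts and 1 for transcripts of the NONCODE database. Each deposited table also gives the mapped total of the library as a read count, the same in each of its rows. Values in rpm (RPM, reads scaled by the mapped total) and rpkm (rpm per kilobase of transcript) were deposited beside the counts, and both could be recomputed from the counts, the mapped total and the transcript length. The authors named neither the aligner nor the annotation version. Transcripts without a read were not listed and were set to 0. Over the 14 libraries the tables listed 13402 GENCODE transcripts of 7243 gene names and 19891 NONCODE transcripts. A read in several overlapping transcripts was counted in each of them. Messenger RNAs have no rows, and neither has AR, so the AR level after siAR could not be examined. Of the GENCODE rows, 9393 have the same position in GENCODE 44 on GRCh37, which gave newer names and overlaps with coding exons. NONCODE starts were raised by 1 to the numbering of GENCODE. Of 12 unspliced NONCODE rows that lie inside a row of the other strand, 8 had more reads than the row around them, so the strands had been counted apart.

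For GENCODE, each gene was measured by the transcript with the largest total over the 14 libraries, a choice made after the tables were seen. Each NONCODE transcript was tested by itself. Counts were fitted with edgeR 4.0.16 in R 4.3.3, with the mapped total as library size, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and quasi-likelihood F-tests (two-sided). Treatment (5 levels) and cell line (4 levels) entered the fit of all 14 libraries, which left 6 residual degrees of freedom. The spread behind each test is that between lines in their response, since no line and treatment had a replicate. The contrasts were DHT against vehicle (4 lines), DHT with bicalutamide against DHT, DHT with siAR against DHT, vehicle with siAR against vehicle, and the siAR by DHT interaction (LNCaP and VCaP for these 4). The LTAD state and its interaction with DHT were fitted on the 8 vehicle and DHT libraries with origin as a block, with 3 residual degrees of freedom. Adjusted p is Benjamini-Hochberg over the features of 1 table and contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The fit tested 3921 GENCODE genes and 12540 NONCODE transcripts, and the LTAD fit 3511 and 11546.

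Within 1 line, ratios were computed from TMM-scaled counts with a prior count of 0.5 for genes with at least 100 counts in 1 of the 2 libraries, with exact 95% confidence intervals from the binomial distribution of the 2 counts. A fold against a library with 0 counts is a lower bound against 3 counts, which is 0.0256 to 0.0388 rpm at these depths. Intervals and bounds cover counting error only, since reads made by PCR are not independent molecules.

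Of 20 gene lists fixed before the data were examined, 4 had at least 5 members in the tables: lncRNAs known in prostate cancer, snoRNA host genes, androgen response genes and mitochondrial transcripts. Coding genes were represented by NONCODE rows of which at least 80% of the span lies in the exons of the gene on its strand. This gave 13 of the 101 androgen response genes. The other 16 lists, among them sterol synthesis, cell cycle, apoptosis, neuroendocrine and interferon genes and markers of other cell types, could not be tested. Lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01 and again with an estimated one, and p was adjusted over the 4 lists of a contrast. Within each line the median log2 ratio of a list was set against 10000 random lists of the same size drawn from features of similar level.

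The genes named were chosen by a rule fixed before the data were examined. For each contrast it takes the 10 highest and 10 lowest log2 fold changes among GENCODE genes with adjusted p under 0.05, the same sign in every line of the contrast and a mean of at least 1 CPM (counts over the mapped total, the same as rpm). NONCODE transcripts follow the same rule with 5 in each direction. Where none passed, the 5 smallest p in each direction were named as not passing. The 2 to 4 list members with the smallest p are named too, and 17 genes, KLK3, SOCS2-AS1, CTBP1-AS and PCA3 among them, were to be given for DHT wherever the tables hold them. Rows for KLK2, TMPRSS2, FKBP5, NKX3-1, ERG and PCAT14 are not there. Genes named outside the rule are said to be so. Some genes whose clone names read as a number in exponent form are given by their GENCODE 44 name or Ensembl gene identifier instead.

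Alternatives covered RLE size factors, DESeq2 1.42.0, no filter, a filter of at least 1 CPM, here with TMM, in 4 libraries, no line term, leaving out each line, the 8 vehicle and DHT libraries alone, the 10 LNCaP and VCaP libraries alone, and the NONCODE table. Mapped totals without TMM, every GENCODE transcript, both LTAD lines set against LNCaP and a wider choice of rows for androgen response genes were added after the data were seen. The pipeline was tested on simulated data with known changes. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Rows of the Y chromosome and XIST were left out of all listed values.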

Results

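Reads of non-coding transcripts were counted in 14 libraries of prostate cancer cells, to find lncRNAs regulated by androgen. LNCaP and VCaP each gave a library for vehicle, DHT, DHT with bicalutamide, DHT with siAR and vehicle with siAR. The lines labelled LTAD and VCaP-LTAD each gave a vehicle and a DHT library. Libraries held 77390018 to 117280991 mapped reads, with a median of 98292166. Reads in a listed GENCODE transcript made up 1.56 to 2.49% of the mapped reads, and those in a NONCODE transcript 11.1 to 13.3%. MALAT1 took from 5.10% (LTAD vehicle) to 33.9% (VCaP DHT) of the GENCODE reads. Every line and treatment had a single library, so the errors given are standard errors of the fit, in which the cell lines serve as replicates. The fit treats the lines as independent, but they are not fully so, since LTAD was taken to stem from LNCaP. Across genes, median Spearman correlations with LNCaP libraries were 0.849 for LTAD, 0.883 for VCaP-LTAD and 0.478 for VCaP. Standard errors and adjusted p may therefore be too small, and by how much was not tested.

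The library pair labelled VCaP-LTAD resembled LNCaP in its lncRNAs. Across genes, its libraries had a median Spearman correlation of 0.883 with LNCaP libraries and 0.491 with VCaP libraries (10 library pairs each; genes are not independent replicates). VCaP-only genes (40) had at least 1 rpm in each of the 5 VCaP libraries and at least 16-fold more than in any LNCaP library, a rule chosen after the data were seen, and LNCaP-only genes (46) the reverse. The VCaP-only genes lay at a median of 1.78% of their VCaP level in the VCaP-LTAD vehicle library, and the LNCaP-only genes at 91.2% of their LNCaP level. In the vehicle library of LTAD, 13 short structured RNAs listed after some of them had been seen to be low there, RPPH1 (the RNA of ribonuclease P) and RNU12 (a minor spliceosomal RNA) among them, lay 7.72-fold below the lowest other vehicle library in the median. These libraries entered the comparisons under their labels.

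DHT against vehicle asks which lncRNAs respond to androgen across the 4 lines. DHT raised LINC00844, an androgen-induced prostate lncRNA, by 3.65 ± 0.48 on the log2 scale (adjusted p = 0.00054), from 0.110 to 2.01 rpm in LNCaP and from 0.864 to 13.6 rpm in VCaP. SOCS2-AS1, the antisense RNA of the cytokine signalling suppressor gene SOCS2, rose by 3.53 ± 0.57 (adjusted p = 0.0024), and its level went from 0.253 to 13.4 rpm in VCaP, 65.3-fold higher (95% CI 43.7 to 102), and 3.68-fold higher in LNCaP (3.0 to 4.5). RP11-314O13.1, now named ARLNC1, a lncRNA known to stabilise AR messenger RNA, rose by 2.70 ± 0.52 (adjusted p = 0.011). DHT lowered ENSG00000243081 (-4.34 ± 0.59, adjusted p = 0.00054) and RP11-319F12.2, now LINC02672 (-4.02 ± 0.56, adjusted p = 0.00054). Both were lower in the DHT library of each of the 4 lines.

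The edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment, called 30 of 3921 genes, of which 21 rose and 9 fell. Among them 24 (18 up and 6 down) moved the same way in all 4 lines with a mean of at least 1 rpm. The highest 10 of the 18 also included RP1-288H2.2, antisense to SMIM41 (3.58 ± 0.66), RP11-191G24.1 or EPS15-AS1 (2.54 ± 0.42), AC124944.2 or TNK2-AS1 (2.43 ± 0.51), FAM13A-AS1 (2.19 ± 0.47) and AP000295.7 or IL10RB-DT (2.13 ± 0.41). ENSG00000261061 (2.17 ± 0.37) lies wholly within exons of CENPN, a kinetochore gene, and RP11-67L3.6 (1.89 ± 0.42) overlaps exons of DHCR24, which makes cholesterol. The other genes that fell were SSTR5-AS1 (-1.95 ± 0.33), antisense to a somatostatin receptor gene, RP11-159H10.3 or SLCO5A1-AS1 (-1.52 ± 0.32), PRKAG2-AS1 (-1.35 ± 0.30) and HCP5 (-1.09 ± 0.25), a lncRNA of the major histocompatibility region. Adjusted p for these 11 genes was 0.0028 to 0.045. On hg19, LINC00844 lies on chromosome 10 from 60759386 to 60761303, SOCS2-AS1 on chromosome 12 from 93936239 to 93965544, RP11-319F12.2 on chromosome 10 from 54733248 to 54735575 and ENSG00000243081 on chromosome 3 from 112115494 to 112127981.

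**Figure D1:**
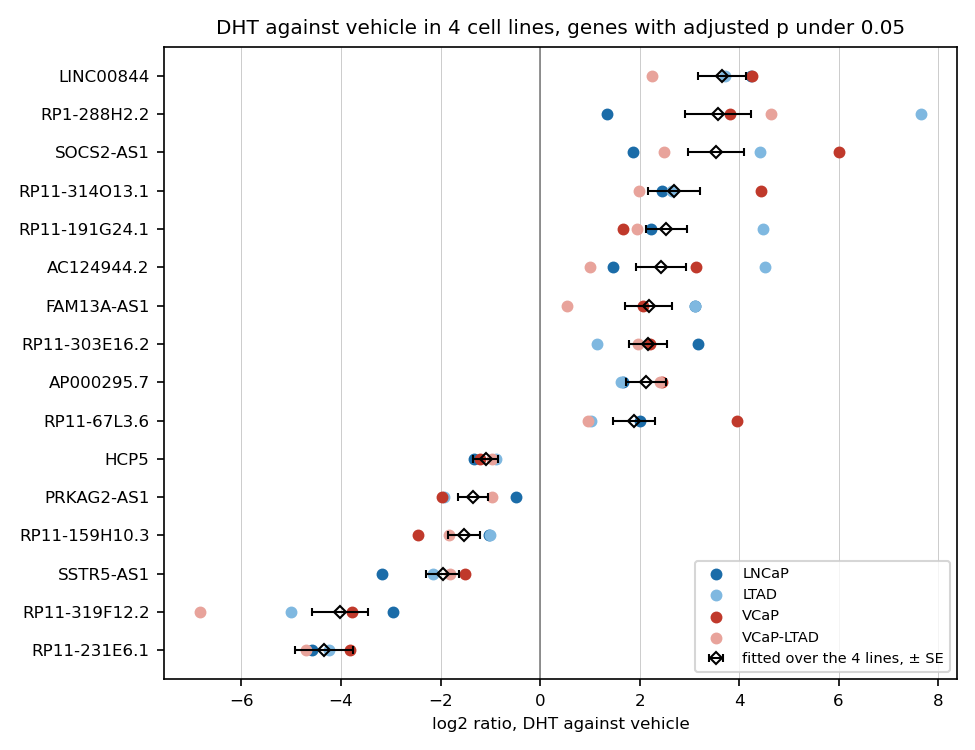
The plot gives the log2 ratio of DHT to vehicle on the x axis for 16 GENCODE genes chosen by the naming rule, with a coloured point per cell line (1 library per treatment) and a diamond for the fitted value with its standard error. All 10 genes above 0 and all 6 below 0 lie on the same side in each of the 4 lines.

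Called genes outside the naming rule had no reads, or too few, in some lines, and were named after their values were seen. CTB-167B5.2, which lies within exons of the metalloreductase gene STEAP4, had 61 reads in VCaP with vehicle and 9033 with DHT, 169-fold higher (131 to 221). It was at least 52.2-fold higher in LNCaP and at least 144-fold higher in the line labelled VCaP-LTAD, and LTAD had no read of it in either library. AC064834.1 went from 0 to 354 reads in VCaP, at least 134-fold higher, and CTD-2126E3.1 was 10.8-fold higher there. RP4-749H3.1 or LINC01141 went from 339 reads to 0 in VCaP, at least 99.2-fold lower. FZD10-AS1, named after the Wnt receptor gene FZD10, was 34.4-fold lower there and RP11-90K6.1, which overlaps an exon of CD200, 61.2-fold lower. These folds within a line carry no test. In the fit of all lines, adjusted p was 1.0e-07 for CTB-167B5.2, 0.00054 for RP4-749H3.1, 0.0048 for FZD10-AS1, 0.0055 for AC064834.1 and 0.033 for CTD-2126E3.1 and RP11-90K6.1. Outside VCaP, vehicle and DHT libraries had at most 3 reads of AC064834.1 and at most 6 of FZD10-AS1. Their p therefore rests on VCaP and says little about the spread between lines.

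Of 17 genes to be given by name, KLK3, which encodes prostate-specific antigen, was seen through the NONCODE row n335996 in its exons and rose by 2.48 ± 0.42 (adjusted p = 0.0043), from 140 to 561 rpm in LNCaP. For CTBP1-AS, an antisense lncRNA that represses CTBP1, and SCHLAP1, the NONCODE row with most reads overlapping the gene on its strand was taken. No overlap with its exons was required, so such a row may count other transcripts. The CTBP1-AS row (n339786) rose by 2.26 ± 0.33 (adjusted p = 0.0017). PCA3, a urine marker of prostate cancer, gave 3.41 ± 1.30 (adjusted p = 0.33) and was higher with DHT in each of the 4 lines, by 8.56-fold in LNCaP (4.89 to 16.2). PCAT1 gave -1.95 ± 0.53 (adjusted p = 0.098), with 16.1-fold less in LTAD (7.62 to 40.6), 13-fold less in VCaP (11 to 16), 3.69-fold less in VCaP-LTAD (2.90 to 4.75) and 1.04-fold less in LNCaP (0.972 to 1.12). The log2 values of PCGEM1 (-0.36), DRAIC (0.31), NEAT1 (0.28), MALAT1 (0.60) and SCHLAP1 (n365301, 0.22) did not pass the test, with adjusted p from 0.21 to 0.96. The DRAIC value joins opposite directions. With DHT it was 1.39-fold lower in LNCaP (1.28 to 1.51) and 1.30-fold lower in LTAD (1.16 to 1.46). It was 2.58-fold higher in VCaP (2.45 to 2.72) and 1.77-fold higher in VCaP-LTAD (1.66 to 1.89).

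Androgen response genes rose together. Of 11 tested, 8 rose (9 adjusted over the list alone), among them STEAP4 through the same reads as CTB-167B5.2, PMEPA1 (2.08 ± 0.38), an inhibitor of TGF-beta signalling, SAT1 (1.59 ± 0.30), which acetylates polyamines, and HOMER2 (1.24 ± 0.21), and the camera test had adjusted p = 3.6e-15 (adjusted p = 0.0059 with an estimated correlation). Of 32 lncRNAs known in prostate cancer, 4 rose, LINC00844, SOCS2-AS1, ARLNC1 and PART1 (1.65 ± 0.26), while adjusted over the list alone 7 rose and 4 fell. Their median log2 fold change was -0.09 and their mean 0.32, and camera placed the list up with adjusted p = 0.042 (adjusted p = 0.15 with an estimated correlation). None of 11 snoRNA host genes passed (1 fell adjusted over the list alone), with GAS5 at -0.75 ± 0.22 (adjusted p = 0.15). Camera placed these hosts down with adjusted p = 0.0014, against adjusted p = 0.31 with an estimated correlation, and their median log2 ratio was -1.08 in VCaP and -0.49 in VCaP-LTAD but -0.015 in LTAD and 0.17 in LNCaP. The 5 mitochondrial transcripts had a camera adjusted p = 0.71.

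Of 12540 NONCODE transcripts, 130 rose and 62 fell, at 91 and 35 loci. The highest by the naming rule were n377170 in the PCSEAT locus (5.95 ± 1.04), n367575 on chromosome 4 (4.10 ± 0.46), n341186 within THSD7A (3.89 ± 0.52), n345709 next to RP1-288H2.2 (3.87 ± 0.64) and n383552 on chromosome 19 (3.86 ± 0.76). The lowest were 4 overlapping transcripts of LINC02672, n371882, n372193, n372194 and n372364 (-4.00 to -3.46), and n334838 within SYTL2 (-2.35 ± 0.54). Adjusted p for these 10 was 0.00018 to 0.037. Of the 192 NONCODE transcripts called, 51.6% overlap a coding exon on their strand, against 32.0% of those tested. Of the 30 GENCODE genes called, 9 (30%) overlap one, against 18.7% of those tested. Such rows also count reads of messenger RNA. The called count depended on the lines in the fit: without VCaP-LTAD 13 GENCODE genes were called (12 of the 30), without LTAD 20 (all of them among the 30), without LNCaP 61 (27 of the 30) and without VCaP 94 (24 of the 30), and DESeq2 called 66 (26 of the 30). With mapped totals in place of TMM 14 rose and 10 fell, and the median log2 fold change of all genes was -0.15 with TMM and -0.30 without.

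DHT against vehicle within each line shows where the responses differed in size or direction, with no test of the difference. Across 752 GENCODE genes, the log2 ratios had the same sign in 46.0% between LNCaP and LTAD (Spearman correlation 0.034). Between VCaP and VCaP-LTAD the share was 65.2% (0.478), and these were the lowest and highest of the line pairs. Of genes with 100 or more reads, 37 were at least 2-fold higher and 48 lower in LNCaP, 107 and 141 in LTAD, 182 and 245 in VCaP, and 74 and 107 in VCaP-LTAD. In LNCaP the highest ratio after CTB-167B5.2 was that of AC079776.3 or LINC01856, from 0 to 113 reads, and RP11-319F12.2 had the lowest. In VCaP, PCAT18 (RP11-17A19.1) went from 0 to 116 reads, at least 44.1-fold higher, while TRHDE-AS1 went from 100 reads to 0, at least 29.3-fold lower. In VCaP-LTAD, RP1-288H2.2 was 27.6-fold higher (12.3 to 76.4) and GPC5-AS1 had 271 reads with vehicle and 14 with DHT. In LTAD the highest ratio was that of RPPH1, 85 reads with vehicle and 23562 with DHT, an RNA of the group low in that vehicle library, and AC141928.1 had the lowest, with 117 and 3 reads. Androgen response genes had median log2 ratios of 1.38 in LNCaP, 0.76 in LTAD, 1.39 in VCaP and 0.80 in VCaP-LTAD, above at least 99.94% of random lists in each line.

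DHT with bicalutamide against DHT asks which responses the antiandrogen opposes. CTB-167B5.2 in STEAP4 had the smallest p (-2.77 ± 0.51, adjusted p = 0.12), with 88.0 rpm under DHT and 30.4 rpm with bicalutamide in VCaP and 1.32 against 0.0638 rpm in LNCaP. RP11-319F12.2 (2.93 ± 0.61, adjusted p = 0.22) was 3.63-fold higher with bicalutamide in LNCaP (2.40 to 5.65) and 9.79-fold higher in VCaP (5.08 to 21.1). ENSG00000243081 was 19.6-fold higher in LNCaP (6.36 to 97.9) and 1.28-fold higher in VCaP (0.672 to 2.46). SOCS2-AS1 gave -1.74 ± 0.69 (adjusted p = 1.0) with 3.61-fold less in LNCaP and 3.38-fold less in VCaP.

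No gene passed the edgeR test for bicalutamide, with 107 genes at an unadjusted p under 0.05 and 10 called by DESeq2, and no NONCODE transcript passed (339 at an unadjusted p under 0.05, 30 by DESeq2). The other genes of smallest p were FZD10-AS1, RP4-749H3.1 and NEFL upward and RP11-446H18.3, AC002467.7, RP1-288H2.2 and RP11-191G24.1 downward. In NONCODE they were n371882, n337901 within SLC6A9, n372193, n372194 and n376891 upward, and n410702 in the RHOU locus, n341270 in STEAP4, n337037 in ADAMTS1, n367575 and n366628 downward. Androgen response genes fell as a list, with a median of -0.52 and no positive value among 11 members (3 adjusted over the list alone, STEAP4, ADAMTS1 and ELK4 having the smallest p), camera adjusted p = 6.3e-09 and adjusted p = 0.045 with an estimated correlation. The KLK3 row gave -0.49 ± 0.53. Camera placed snoRNA hosts up with adjusted p = 0.027 (adjusted p = 0.56 with an estimated correlation), and lncRNAs known in prostate cancer (adjusted p = 0.76) and mitochondrial transcripts (0.12) did not pass. In a simulation on these libraries the test recovered 43% of 4-fold changes for this contrast, against 84% for DHT.

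DHT with siAR against DHT asks which responses siAR opposes, without a control siRNA or a measured AR level. RP11-319F12.2 (LINC02672), lowered by DHT, rose with siAR by 4.41 ± 0.61 (adjusted p = 0.0013), from 0.273 to 5.21 rpm in LNCaP and from 0.0974 to 1.65 rpm in VCaP. ENSG00000243081 rose by 3.85 ± 0.67 (adjusted p = 0.010) and RP11-90K6.1 by 5.33 ± 1.04 (adjusted p = 0.031). CTB-167B5.2 in STEAP4 fell (-3.03 ± 0.52, adjusted p = 0.010), and so did RP11-145M9.4 (-2.86 ± 0.54, adjusted p = 0.024), which lies within exons of the G protein gene GNB4. Named outside the rule, RP4-749H3.1 went from 0 to 368 reads in VCaP, at least 108-fold higher, and FZD10-AS1 was 45.9-fold higher there.

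In all, edgeR called 7 genes, 5 up and 2 down, and 20 NONCODE transcripts up and 9 down, at 9 loci each way. The NONCODE rows were n363305 over LINC01141, 4 of LINC02672 (n371882, n372193, n372364 and n372194, 3.65 to 4.36), and downward n341270 in STEAP4 (-3.03 ± 0.50), n406527 in the CSGALNACT1 locus (-2.32 ± 0.41), n410702 in the RHOU locus (-2.06 ± 0.31), n338674 in the locus of GREB1, a steroid receptor target (-1.77 ± 0.27), and n334612 in that of ABCC4, a drug and prostaglandin exporter (-1.75 ± 0.28), all with adjusted p from 0.011 to 0.023. LINC00844 gave -3.04 ± 0.64 (adjusted p = 0.059), PART1 -1.54 ± 0.35 (adjusted p = 0.12), ARLNC1 -1.98 ± 0.68 (adjusted p = 0.45) and SOCS2-AS1 -1.71 ± 0.69 (adjusted p = 0.57). Androgen response genes fell as a list (median -1.17, no positive value among 11, 1 passing over all transcripts and 10 over the list alone; camera adjusted p = 1.3e-14, adjusted p = 0.0053 with an estimated correlation), with KLK3 at -2.35 ± 0.58 (adjusted p = 0.12) and SAT1 at -1.88 ± 0.39 (adjusted p = 0.068). Camera did not call lncRNAs known in prostate cancer (adjusted p = 0.17; 2 fell adjusted over the list alone), snoRNA hosts (0.12) or mitochondrial transcripts (0.73). DESeq2 called 29 genes, with 4 of the 7. Without VCaP-LTAD edgeR called 3 (2 of the 7), and 0 with at least 1 CPM required in 4 libraries.

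**Figure D2:**
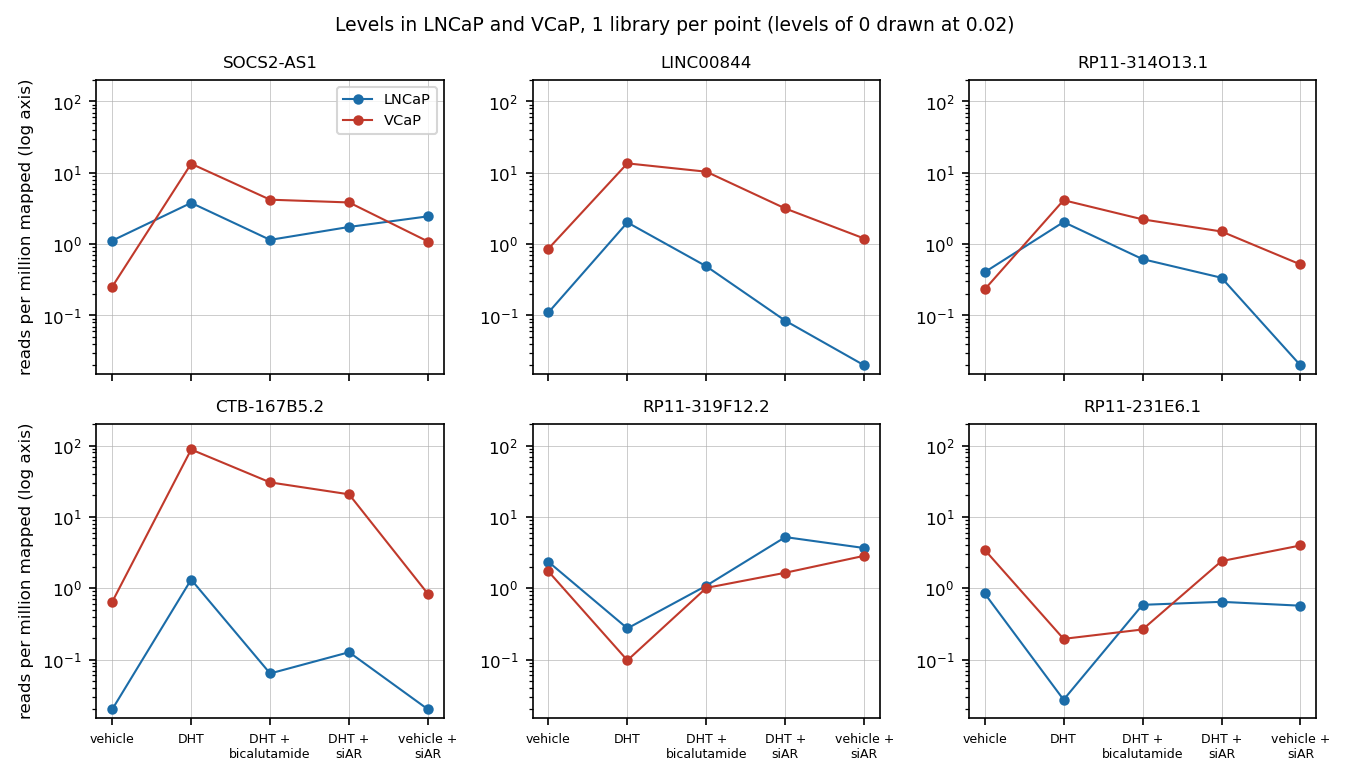
Levels in rpm (log axis) are plotted for 6 genes over the 5 treatments in LNCaP and VCaP, with 1 library per point and levels of 0 drawn at 0.02. SOCS2-AS1 in VCaP stands at 0.253 with vehicle, 13.4 with DHT, 4.20 with bicalutamide and 3.84 with siAR, and RP11-319F12.2 in LNCaP at 2.34, 0.273, 1.08 and 5.21.

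Vehicle with siAR against vehicle asks what siAR does without added androgen, again without a control siRNA. KLK3 (n335996) gave -1.15 ± 0.53 (adjusted p = 1.0), with 140 rpm under vehicle and 33.1 rpm with siAR in LNCaP and 32.9 and 24.9 rpm in VCaP. SOCS2-AS1 gave 1.30 ± 0.67, with 1.12 and 2.46 rpm in LNCaP and 0.253 and 1.09 rpm in VCaP. RP11-319F12.2 had 2.34 and 3.66 rpm in LNCaP and 1.72 and 2.85 rpm in VCaP, and PART1 2.82 and 2.71 rpm in LNCaP and 11.4 rpm in both VCaP libraries.

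No gene passed in edgeR (111 at an unadjusted p under 0.05, 5 by DESeq2) and no NONCODE transcript (360 and 15). Genes of smallest p were RP11-357H14.19, RP11-302J23.1, CTD-2589M5.4, BX004987.5 and HOXC-AS5 upward and RP11-524O1.4, ENSG00000258028, AC124944.2, RP11-183M13.1 and SNHG9 downward, all at adjusted p = 1.0. In NONCODE they were n410877 in CLU, n370155, n387668, n386148 in METRN and n405456 in CCDC32 upward, and n407162 in TFDP1, n383439 in ZNF730, n333275 in CCNB1, n342319 in ARF6 and n338211 downward. Androgen response genes had a median of -0.22 (2 of 11 positive), camera adjusted p = 0.042 and adjusted p = 0.42 with an estimated correlation, with HOMER2 at -0.74 ± 0.29 and GUCY1A3 at -0.85 ± 0.38. Mitochondrial transcripts had a median of -0.31, camera adjusted p = 0.013 and adjusted p = 0.42 with an estimated correlation, MT-ATP6 standing at -0.46 ± 0.25. Neither lncRNAs known in prostate cancer (adjusted p = 0.77) nor snoRNA hosts (0.26) were called. Leaving out VCaP or LNCaP left 1 library pair for this contrast, which has no spread of its own, so counts of such fits are not read here.

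The siAR by DHT interaction asks whether siAR acts differently with and without androgen. RP4-749H3.1 (LINC01141) was the gene called (8.94 ± 1.46, adjusted p = 0.049). In VCaP it had 3.57 rpm with vehicle, 5.66 with vehicle and siAR, none with DHT and 3.74 with DHT and siAR, and LNCaP had at most 0.0317 rpm. RP11-319F12.2 (4.03 ± 0.83, adjusted p = 0.20), ENSG00000243081 (4.06 ± 0.89, adjusted p = 0.25), CTB-167B5.2 (-3.45 ± 0.78, adjusted p = 0.29) and SOCS2-AS1 (-3.00 ± 0.90, adjusted p = 1.0) did not pass. Androgen response genes were lower as a list (median -0.95, 1 of 11 positive, 4 lower adjusted over the list alone, among them STEAP4 and SAT1; camera adjusted p = 2.7e-08, adjusted p = 0.034 with an estimated correlation). The other 3 lists had camera adjusted p of 0.42 (lncRNAs known in prostate cancer and snoRNA hosts) and 0.12 (mitochondrial transcripts). Further genes of smallest p were FZD10-AS1, ENSG00000235021, AC020571.3, AC002467.7 and PART1, and in NONCODE, where none passed (488 at an unadjusted p under 0.05, 20 by DESeq2), n363305, n376891, n376685, n339647 in GPR149, n371882, n406427 in TBRG1, n346438, n406527, n341270 and n409653 in SORD. Of the 2 lines with siAR, the RP4-749H3.1 call rests on VCaP, and its adjusted p lies next to the threshold. The pair labelled VCaP-LTAD, with 25 reads under vehicle and 0 with DHT, also enters the DHT and vehicle terms. The 10 LNCaP and VCaP libraries alone gave 0 calls. DESeq2 called 3 genes, RP4-749H3.1 not among them, and edgeR without VCaP-LTAD called 0, while 148 genes had an unadjusted p under 0.05 in the fit of all lines.

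Whether bicalutamide or siAR opposed the DHT response was also counted over the called genes. Of the 30 DHT genes, 29 had the opposite sign with bicalutamide and 30 with siAR, and 6 of the 30 also passed for siAR. The DHT libraries of LNCaP and VCaP enter both contrasts, and part of this overlap is to be expected from them: 20 simulations with no effect had on average 0.7 DHT calls, of which 0.15 also passed for siAR. Independent lists without shared libraries would overlap by 0.022. The simulations gave 85.8% and 85.2% opposite signs among their top 30 genes (at most 93.3% and 96.7%). Across all genes, the fold changes for bicalutamide had a correlation of -0.362 with those for DHT, no stronger than the -0.364 simulated with no effect, and those for siAR -0.568 against -0.365. The covariances were -0.776 for bicalutamide and -1.26 for siAR, against -0.480 and -0.482 simulated. A further set was the 86 genes called in LTAD and VCaP-LTAD alone, lines without a bicalutamide or siAR library. These had opposite signs in 74.4% for bicalutamide and 84.9% for siAR, against 54.9% and 57.1% of all genes. Among these 86, the 52 raised by DHT had a median of -1.06 with siAR and the 34 lowered 0.71. In NONCODE, where transcripts overlap, the shares were 80.9% and 87.1% of 272, against 55.3% and 58.5% of all transcripts. In a fit of all lines, the LTAD and VCaP-LTAD libraries also help to set the DHT and vehicle terms. Part of these shares may therefore stem from the fit itself, and they are no independent test.

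LTAD state against parental cells asks how the LTAD-labelled lines differ from LNCaP and VCaP without added androgen. The labels give these lines a higher percentage of stripped serum than LNCaP and VCaP, and no length of culture. Effects of long culture therefore cannot be told apart from those of the serum percentage, here or in the LTAD by DHT interaction. MALAT1, the abundant nuclear lncRNA, gave -1.55 ± 0.28 (adjusted p = 0.99), with 795 rpm in LTAD against 2311 rpm in LNCaP and 2809 rpm in VCaP-LTAD against 5405 rpm in VCaP. HOXA11-AS was 18.6-fold lower in LTAD than in LNCaP (11.4 to 32.5) and 6.86-fold lower in VCaP-LTAD than in VCaP (6.34 to 7.42), and RP11-145M9.4 in GNB4 was 6.18-fold and 9.84-fold higher. KLK3 (n335996) had 0.247 rpm in LTAD, 140 in LNCaP, 279 in VCaP-LTAD and 32.9 in VCaP. LINC00161 went from 3713 reads in LNCaP to 0 in LTAD, at least 1475-fold lower.

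No gene passed in edgeR (112 at an unadjusted p under 0.05, 12 by DESeq2) and no NONCODE transcript (480 and 49), and a simulation recovered 0% of 4-fold changes with 3 residual degrees of freedom. Setting both LTAD lines against LNCaP, an alternative added after the data were seen, also called 0. Leaving out 1 line at a time left 1 library pair per state and called 47 (without VCaP-LTAD), 243 (VCaP), 646 (LTAD) and 919 genes (LNCaP). Within single lines, 448 genes differed by at least 2-fold between LTAD and LNCaP, 946 between VCaP-LTAD and VCaP, and 235 between VCaP-LTAD and LNCaP. The other genes of smallest p were RP11-15F12.1, RP11-143M1.4, RP11-744K17.9 and RP11-43F13.3 upward and LINC00617, CYP4F8 and CTC-523E23.5 downward, and in NONCODE n339877, n340493 in MAP1B, n339050 in PDE1A, n383439 and n407465 upward and n372654, n335256 in CPLX2, n344502, n339648 in GPR149 and n369018 downward. LINC00617 went from 4901 reads in VCaP to 1 in VCaP-LTAD and had none in LNCaP and LTAD. Among 11 snoRNA host genes 5 were lower adjusted over the list alone, SNHG8 (-2.08 ± 0.54), ZFAS1 (-1.91 ± 0.52), SNHG5 (-3.14 ± 0.93) and GAS5 (-2.27 ± 0.70) with the smallest p, none of them past the test over all genes (camera adjusted p = 5.5e-09, adjusted p = 0.22 with an estimated correlation). Of 31 lncRNAs known in prostate cancer 1, MALAT1, was lower adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.21 with an estimated correlation). Androgen response genes and mitochondrial transcripts both had a camera adjusted p = 0.083. These values carry the LNCaP-like profile of the VCaP-LTAD libraries and the low short RNAs of LTAD vehicle.

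**Figure D3:**
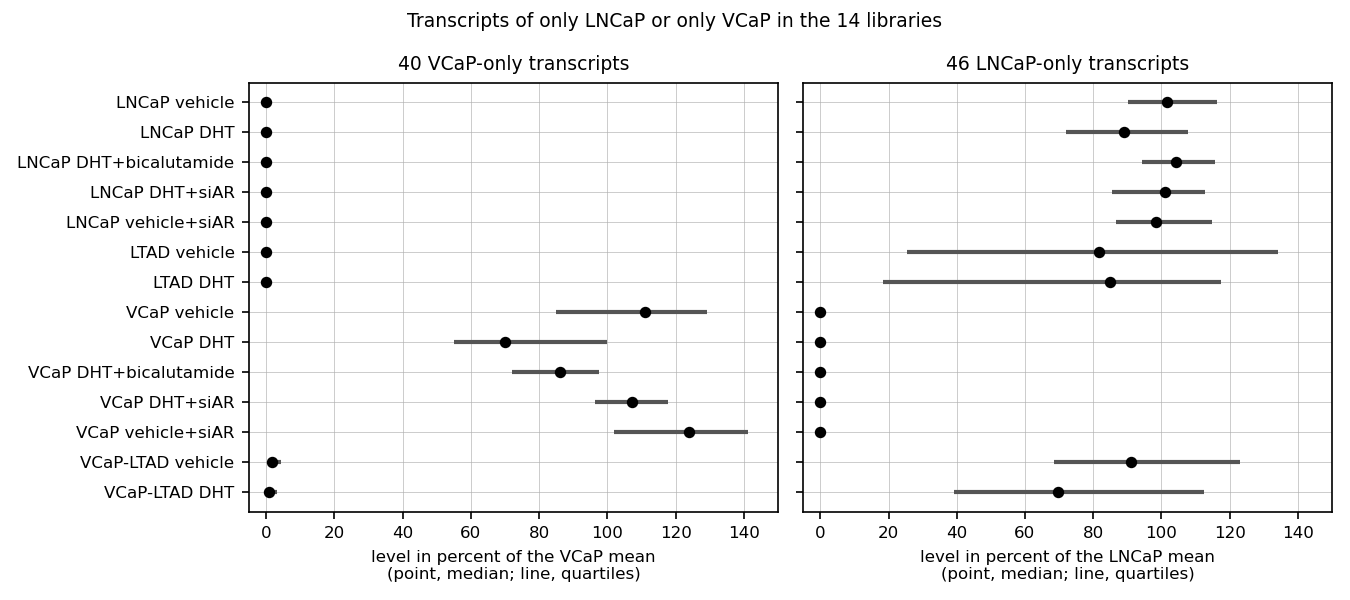
For 40 VCaP-only and 46 LNCaP-only transcripts, the x axis gives the level in percent of the mean of VCaP or LNCaP, with the median as a point and the quartiles as a line for each of the 14 libraries. The VCaP-LTAD libraries stand at medians of 1.78% and 0.956% for the VCaP-only transcripts and 91.2% and 69.8% for the LNCaP-only transcripts.

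The LTAD by DHT interaction asks whether the LTAD state alters the androgen response. SCARNA2 (3.37 ± 1.17, adjusted p = 1.0), a short RNA of the group low in LTAD vehicle, and RP11-459C13.1 (-8.84 ± 2.70, adjusted p = 1.0) had the smallest p upward and downward. SOCS2-AS1 (-0.33 ± 1.59), ARLNC1 (-0.92 ± 1.24) and KLK3 (-0.51 ± 3.59) did not pass. No gene passed in edgeR (20 at an unadjusted p under 0.05, 1 by DESeq2) and no NONCODE transcript (47 and 0). The other genes of smallest p were RP11-73M18.9, LINC00470, RP11-17M16.2 and CTD-2037L6.2 upward and RP11-173A16.2, RP11-540A21.2, RP11-141J13.3 and RP11-216B9.6 downward. In NONCODE they were n335256, n203786, n364198, n409181 and n383255 upward and n372193, n337685, n376218, n372668 and n380245 downward. Camera adjusted p was 0.098 for androgen response genes (3 of 11 positive) and 0.37 for each of the other 3 lists. Standard errors of the GENCODE genes named were 1.17 to 4.21, so differences of several fold were not detectable. Leaving out any line left the LTAD or the parental state with 1 library pair, so counts of such fits are not read here.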

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

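The tests on the identity of the VCaP-LTAD libraries, the test of a DHT effect on the short RNAs and the counts of splits were chosen only after the result was seen, and so was the reading of the poly(A) test for a value above its range. The other tests in this part were written before.

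RP4-749H3.1 (LINC01141) was singled out because its response to siAR differed between DHT and vehicle in an interaction test, with a fitted log2 value of 8.94. This value rests on VCaP, where the DHT library had no read, and the vehicle and DHT libraries labelled VCaP-LTAD also enter it.

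The 2 libraries labelled VCaP-LTAD carried an LNCaP-like set of lncRNAs. VCaP-only transcripts lay at a median of 1.78% of the VCaP level in the vehicle library and LNCaP-only transcripts at 91.2% of the LNCaP level, which argues against VCaP cells altered by culture. An exchange of labels within the series would place the VCaP-only transcripts in a library labelled LNCaP or LTAD. The rule that chose these transcripts already keeps them low in every LNCaP library, so only an exchange with LTAD was open to this test. Their highest median was 0.0215%, in LTAD vehicle, which argues against an exchange with LTAD. LNCaP cells with a small share of VCaP cells cannot be told apart from the rest, because of 18 abundant VCaP-only transcripts only 3 (LINC00617, RP1-310O13.12 and RP11-13L2.4) lay under 10% of the pooled share in both libraries. A wrong label, or a sample from outside the series, stays open, and so does an origin of this line from LNCaP that the labels do not exclude.

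Short structured RNAs were low in the vehicle library of LTAD, with RPPH1 at 0.725 rpm there and 45.3 to 280 rpm in the other 13 libraries. The median of the 13 RNAs lay 7.72-fold below the lowest other vehicle library. A DHT effect in LTAD cells cannot be told apart from a fault of the vehicle library, because the list was written after some of its members had been seen low there and LTAD has 1 library per treatment. Poly(A) selection would lower intronic RNA too. The share of sense_intronic reads was 188% of the lowest other library, above all 13 others, a side that the written bound had not foreseen. It was 1.13% of the GENCODE counts without MALAT1, against 1.05% in VCaP DHT and 0.602% in LNCaP vehicle with siAR, the highest and lowest others. This class holds transcripts annotated within introns, and whether they follow intronic RNA at large was not tested. A loss of short inserts would lower other transcripts under 400 nt, and 129 of them had a median log2 ratio of 0.15 to the other libraries. These lengths are those of the annotated rows, and the rows of RPPH1 (638 nt) and RNU12 (664 nt) are themselves longer than 400 nt. Annotated length thus did not set the low RNAs apart, and the comparison cannot decide on such a loss. Neither poly(A) selection nor a loss of short inserts is settled by these values. A loss of these particular RNAs in extraction or depletion, or a state of the cells, stays open as untested.

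For DHT against vehicle, the 8 vehicle and DHT libraries were also divided in all 35 ways into groups of 4, of which 34 could be fitted. The bicalutamide and siAR libraries stayed in each fit under their own labels. Since vehicle and DHT libraries are paired by line, the real split compares with the 8 splits that part the pair of every line, itself included, which are too few for a share under 0.05. Of these 8 splits 1, the real one, called 30 GENCODE genes and the highest other called 1, and for NONCODE the values were 192 and 1. The other splits left at least 2 lines whole, so that fewer lines carried the comparison, and called at most 6 genes and 79 transcripts.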

How the results depend on the processing

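Mapped totals without TMM, every GENCODE transcript, both LTAD lines set against LNCaP and the wider choice of androgen response rows were chosen after seeing the data; the other alternatives were planned. Over 61 named genes, 685 values under alternatives kept direction and side of the threshold in 477 cases, fell short of the threshold in 198, passed it anew in 7, moved as a count in 1 (14 of 30 androgen response rows higher with the wider choice) and changed sign in 2: SCHLAP1 with DHT (-0.045 with only the 10 LNCaP and VCaP libraries) and DRAIC (-0.0095 without VCaP, in a leave-one-out range up to 0.61 without LNCaP). RLE size factors kept the counts within 1.5 times. The cause of a changed count was not tested, except that fewer libraries or genes, or more genes, entered where an alternative says so.

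DESeq2 called 66 genes for DHT, 10 for bicalutamide, 29 for DHT with siAR, 5 for vehicle with siAR, 3 for the interaction, 12 for the LTAD state and 1 for its interaction with DHT, and 382, 30, 121, 15, 20 and 49 NONCODE transcripts for the first 6. Without a filter the counts were 122, 8, 55, 1, 21 and 12 genes for these 6 contrasts and 665, 47, 249, 6 and 81 transcripts for the first 5. With at least 1 CPM in 4 libraries they were 18 genes for DHT and 0 for DHT with siAR and for the interaction, and 0 NONCODE transcripts for DHT with siAR. Without the line term, which leaves the difference between lines in the spread, 0 were called for DHT, DHT with siAR and the interaction. The 8 vehicle and DHT libraries alone gave 9 genes and 96 transcripts for DHT, and the 10 LNCaP and VCaP libraries 9 and 27 for DHT, 3 and 7 for DHT with siAR and 0 genes for the interaction. Every GENCODE transcript gave 48 calls for DHT and 0 for the interaction, mapped totals without TMM 0 for the interaction, and NONCODE 192 for DHT, 29 for DHT with siAR and 0 for the interaction. Without TMM the NONCODE calls split into 96 up and 78 down for DHT (130 and 62 with it) and 18 and 4 for DHT with siAR (20 and 9), and TMM took out a shift between DHT and vehicle of -0.339 in VCaP and -0.052 in LTAD.

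Leaving out each line in turn gave 13 to 94 genes for DHT, 0 to 8 for bicalutamide, 3 to 38 for DHT with siAR, 0 to 55 for vehicle with siAR, 0 to 29 for the interaction, 47 to 919 for the LTAD state and 1 to 33 for its interaction with DHT. For NONCODE the ranges were 98 to 421, 0 to 29, 17 to 124, 0 to 113, 0 to 71, 200 to 3720 and 0 to 347. Where this left a contrast with 1 library pair, that pair was assumed to vary like the other groups.

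With an estimated correlation 7 list calls were lost: lncRNAs known in prostate cancer with DHT (adjusted p = 0.15) and in the LTAD state (0.21), snoRNA hosts with DHT (0.31), bicalutamide (0.56) and in the LTAD state (0.22), and androgen response genes and mitochondrial transcripts for vehicle with siAR (0.42 each). A minimum of 30 reads in place of 100 gave 326 genes changed at least 2-fold in LNCaP, 548 in LTAD, 849 in VCaP and 573 in VCaP-LTAD. Genes chosen in the LTAD-labelled lines had opposite signs in 74.4% for bicalutamide and 84.9% for siAR, and in NONCODE in 80.9% and 87.1%. Depth limits single lines: a library with 0 reads of a transcript allows up to 0.0256 to 0.0388 rpm.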

Other observations

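Further prostate lncRNAs were described within lines, chosen after their values were seen. PCAT18 (RP11-17A19.1) had no read with vehicle in LTAD, VCaP and VCaP-LTAD and was at least 8.59-fold, 44.1-fold and 15.4-fold higher with DHT, against 1.92-fold in LNCaP (95% CI 0.799 to 4.93). POTEF-AS1 (AC018804.3) was 14.4-fold higher with DHT in LNCaP (4.59 to 72.8), 66.1-fold in VCaP (58 against 1 reads, 11.4 to 2655), 2.86-fold in LTAD (0.994 to 9.29) and 1.03-fold in VCaP-LTAD (0.627 to 1.68). HOTAIR, a lncRNA of the HOXC cluster, was 7.10-fold lower with DHT in LNCaP (2.14 to 36.9), 2.48-fold lower in VCaP (1.76 to 3.55), 2.51-fold lower in VCaP-LTAD (1.49 to 4.39) and 1.45-fold higher in LTAD (1.18 to 1.77), and the difference was not tested. H19, an imprinted lncRNA, was 2.64-fold lower in LNCaP (1.37 to 5.40), 2.15-fold lower in LTAD (1.38 to 3.45) and at least 3.22-fold lower in VCaP, with 1 read in each VCaP-LTAD library.

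Coding genes of lists too small to test were seen through 1 row each. VEGFA (n333449), the angiogenic factor, gave 0.86 ± 0.23 with DHT (adjusted p = 0.086), and KIF11 (n333538), a motor of the mitotic spindle, -0.94 ± 0.35 (adjusted p = 0.23). OPRK1 (n335198), an opioid receptor gene known to be repressed by androgen, gave -3.17 ± 1.52 with DHT (adjusted p = 0.41) and 3.04 ± 1.59 with siAR (adjusted p = 0.66). The row n410702 in the RHOU locus had 33.0 rpm with vehicle and 129 rpm with DHT in LNCaP, 67.3 and 422 in LTAD, 29.6 and 174 in VCaP, and 169 and 341 in VCaP-LTAD.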
